A study of Mus musculus with 12 samples.

How the data were processed

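Dorsal hippocampus from 12 male mice was profiled by RNA sequencing, 3 mice in each combination of Mbnl2 genotype (WT or KO) and treatment (house control or trained). Per the labels' protocols, RNA was purified on columns, polyadenylated RNA was isolated and libraries were made with an NEBNext Ultra II kit. Each library was deposited by the authors as a file of raw counts, whole numbers of reads per gene symbol for 24421 genes with no rows for unassigned reads. The submitters' processing notes name cutadapt 1.18, Bowtie2 2.3.4.2, TopHat2 2.1.1, HTSeq 0.9.1 and DESeq2 1.18.1 and the build mm10. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart by these counts, and reads shared between paralogs are uncertain.

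The authors also deposited 4 tables of pairwise comparisons with 24394 genes each, whose columns hold, per the file headers, a mean normalized count (signal), a log2 fold change, its standard error, a test score, a p-value and an adjusted p-value. Their mean signal lay within 1% of the mean of the 6 compared libraries under median-of-ratios scaling for all genes with a mean signal above 10, so each table rests on 6 libraries. Their log2 fold changes are KO over WT and trained over house control. Each table lacks 27 genes of the count files. Values from these tables are named as the authors' wherever they appear.

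Groups were taken from the labels. Total counts per library ran from 19737929 to 27427076, where 3 counts are 0.152 to 0.109 CPM. Replicate numbers follow accession order and pair no libraries. Animal and library numbers fall into 2 series, with 8 libraries in the first and 4 in the second, spread as 2 and 1 per group. No 2 libraries of a group held identical counts. A chi-square of each pair over genes, per degree of freedom, ran from 15.6 to 111, so all were counted as separate.

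Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15622. Libraries were scaled by TMM, and 1 quasi-likelihood model with 4 group means and robust estimation was fitted to the 12 libraries, leaving 8 residual degrees of freedom. The 7 contrasts were KO against WT within each treatment, trained against house control within each genotype, both mean effects and the interaction. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM values use TMM-scaled library sizes. The standard error of a log2 fold change is the one implied by the F statistic. Exact permutation of 3 against 3 libraries makes 10 splits and cannot give a share below 0.1, which is why the model over all genes was used.

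A set of 38 lists (18 gene lists and 20 marker lists) was fixed before the data were examined. The 36 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over lists within a contrast. Blood markers, of which the filter on low counts left 3 of 10, and mitochondrially encoded genes, of which 0 were in the files, had too few members and were not tested. As a check of sex, Xist was at most 0.514 CPM and Ddx3y at least 55.1 CPM in every library. Named genes followed a fixed rule: Mbnl1, Mbnl2 and Mbnl3; in pairwise comparisons up to 10 genes per direction, and in mean effects up to 5, with the largest change among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups, passing over unnamed genes; and up to 4 members per described list with the smallest unadjusted p. Ttr, Mbp, Slc17a6, Prox1, Gfap, Rasl11b and Npas4, and the immediate early genes given for the interaction, were named after their values were seen. Coordinates are those of the GENCODE annotation of the same build, which matched 96.1% of the tested symbols.

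The gene test was checked on simulated counts with 200 changed genes. For KO against WT in house controls it recovered 22.4% of genes changed 1.5-fold, 61.2% at 2-fold and 87.9% at 4-fold over 15502 genes. For the mean genotype effect it recovered 47.8%, 80.6% and 95.5% over 15488 genes. For the interaction it recovered 2.99%, 37.3% and 69.7% over 15498 genes. These simulated counts had independent spread, without the tissue differences seen between the real libraries. The share recovered also depends on the number of genes changed, so recovery in the real comparisons may be lower. In a simulation of 15469 genes with independent spread, camera called the 1 list that had been raised and 0 others. This does not check correlated lists, and the estimated correlation reached 0.98 for choroid plexus markers between the genotypes in house controls. At the preset correlation, other splits of the libraries between the genotype labels called a median of 14 lists for the mean genotype effect.

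Alternatives were DESeq2 1.42.0, median-of-ratios scaling, no filter on low counts, a mean of at least 1 CPM, non-robust fitting, only the 6 libraries compared, the animal series as a covariate or only its first 8 libraries, a looser threshold of 0.1 for overlaps, and leaving out each library. Chosen after seeing the data were a covariate made from the first principal component of 18 marker means, a fit without 3 house control libraries rich in choroid plexus or thalamus transcripts (which leaves 1 WT house control library and keeps trained libraries as rich in choroid plexus transcripts), a fit without 2 KO libraries rich in striatum, septum and neocortex transcripts, and DESeq2 on 6 libraries.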

Results

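Gene expression was measured in the dorsal hippocampus of male mice on a mixed 129sv/C57BL/6j background, aged 4 to 5 months, by RNA sequencing of polyadenylated RNA. Mbnl2 encodes a muscleblind-like RNA-binding protein that regulates alternative splicing. The 12 libraries, each from 1 mouse, fell into 4 groups of 3: wild type (WT) and Mbnl2 knockout (KO), each as house controls or after training. The labels do not describe the task, the time from training to dissection or the targeted allele, so the comparisons ask which transcripts differed with genotype, with training, and with both together. Total counts ran from 19737929 to 27427076 per library, and 17493 to 18300 genes had at least 1 count. A floor of 3 counts was 0.109 to 0.152 CPM (counts scaled to library size), which covers counting error only.

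Mbnl2 itself (chromosome 14, 120275669 to 120431697, mm10) had a higher gene-level count in every library labelled KO than in every library labelled WT. The 3 WT house control libraries had 338, 315 and 324 CPM, and the WT trained libraries 360, 363 and 365 CPM. The libraries labelled KO had 488, 470 and 454 CPM as house controls and 509, 473 and 542 CPM after training. Over both treatments Mbnl2 was 1.42-fold higher in the KO-labelled libraries (log2 fold change 0.51, SE 0.05, adjusted p = 0.00626 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Within a treatment the edgeR adjusted p was 0.0888 in house controls (0.0446 without WT house control replicate 1) and 0.128 in trained mice, and in the first series of animals alone it was 0.34 over both treatments (log2 fold change 0.50). The authors' deposited tables give Mbnl2 an adjusted p of 6.26e-08 in house controls and 2.97e-05 in trained mice. The count goes against a loss of Mbnl2 transcript in the libraries labelled KO. It sums reads over all exons, the allele is not described in the labels, and a deletion of single exons would leave most of this count in place, so it does not check the genotype labels. Directions below are therefore those of the labels. The paralog Mbnl1 had 89.6 ± 11.3 CPM in WT and 107 ± 7.29 CPM in KO-labelled libraries (SD, n = 6 each). Its adjusted p by edgeR was 0.16 for the mean genotype effect, and the authors' deposited table calls Mbnl1 higher in trained KO mice (log2 fold change 0.38, adjusted p = 0.011). Mbnl3 had at most 1.45 CPM in any library and is not compared further.

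**Figure D1:**
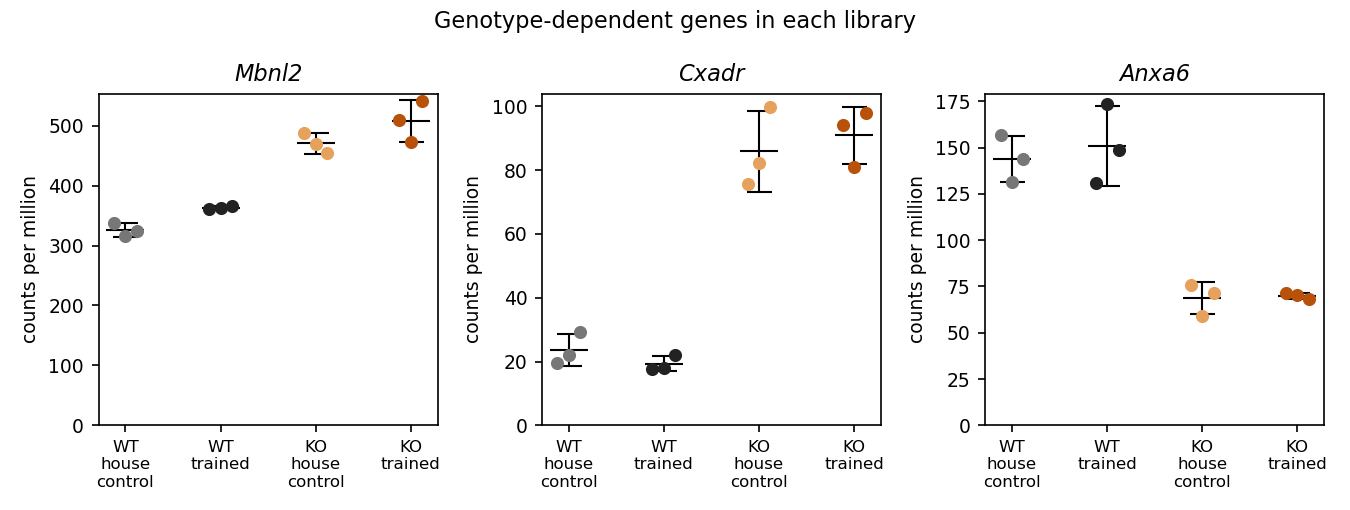
Counts scaled to library size (CPM) of Mbnl2, Cxadr and Anxa6 on linear axes, 1 point per library, with the mean and SD of each group of 3 as bars. The 6 KO-labelled libraries lie above the 6 WT libraries for Mbnl2 and Cxadr and below them for Anxa6.

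In house controls, the KO-labelled mice had far more Cxadr transcript and less Anxa6 transcript than WT mice. Cxadr encodes the coxsackievirus and adenovirus receptor, a cell adhesion protein, and rose 3.64-fold, from 23.6 ± 4.95 to 85.8 ± 12.6 CPM (SD, n = 3 mice each; log2 fold change 1.86, SE 0.16, edgeR adjusted p = 0.00477). Anxa6 encodes annexin A6, a calcium-dependent phospholipid-binding protein, and fell 2.09-fold, from 144 ± 12.5 to 68.8 ± 8.74 CPM (log2 fold change -1.06, SE 0.12, edgeR adjusted p = 0.0258). Cxadr lies on chromosome 16 (78301489 to 78359774) and Anxa6 on chromosome 11 (54979108 to 55033445). These were the only 2 of 15622 genes past the edgeR threshold, beside 1668 at an unadjusted p under 0.05. In each comparison chance gives 781 genes at such an unadjusted p. DESeq2 on the same genes called 155 higher and 47 lower, and the authors' deposited table has 61 higher and 15 lower at an adjusted p under 0.05. Leaving out WT house control replicate 2 ended both edgeR calls, each at an adjusted p = 0.0637. The Anxa6 call also ended by edgeR without WT replicate 3 (adjusted p = 0.136), without KO replicate 2 (0.0875) or 3 (0.111) and without KO replicate 1 (just above 0.05), at log2 fold changes from -1.14 to -0.96, and without WT replicate 1 the higher genes numbered 11. Within the first series of animals, edgeR gave Cxadr a log2 fold change of 1.92 (adjusted p = 0.0267) and Anxa6 -1.09 (adjusted p = 0.816); the second series has 1 library per group. In an edgeR fit of the 6 libraries compared, or without KO replicate 2 of both treatments, 0 genes were called. The same count came without the 3 house control libraries rich in choroid plexus or thalamus transcripts (WT replicates 2 and 3 and KO replicate 3), but that fit compares 1 WT library with 2 KO-labelled ones and assumes that the lone library varies like the other groups.

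Among the lists fixed beforehand, camera with its preset correlation of 0.01 called 18 of 36 in this comparison, and none held with an estimated correlation. Leptomeningeal fibroblast markers were lower (median log2 fold change -0.94, 17 of 17 members negative, adjusted p = 0.337 with an estimated correlation). Their examples were Ogn at -1.64 (SE 0.45) and Ptgds at -2.06 (SE 0.60), neither called over all genes nor adjusted over the list alone. Choroid plexus markers had a median of -1.98, with all 19 members negative and 0 called either way, and an adjusted p = 0.655 with an estimated correlation. The list of presynaptic vesicle and release machinery (median 0.25, 39 of 45 members positive) and that of voltage-gated calcium, sodium and potassium channels (median 0.22, 45 of 58 positive) lay higher, with 0 and 1 members called adjusted over the list alone. Both had an adjusted p = 0.337 with an estimated correlation. Ttr, the transthyretin transcript of the choroid plexus epithelium, was at 7182 and 13366 CPM in WT house control replicates 2 and 3, against 57.9 CPM in replicate 1 and 1921, 36.1 and 2306 CPM in the KO-labelled house controls. Without the 3 house control libraries rich in choroid plexus or thalamus transcripts, which leaves 1 WT library, the medians of the presynaptic and channel lists were 0.04 and 0.01 (camera adjusted p = 0.837 for both). The call of choroid plexus epithelium markers ended without WT replicate 3 (median -0.95, camera adjusted p = 0.283) or KO replicate 2 (median -1.49, camera adjusted p = 0.154).

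In trained mice the genotypes differed in the same 2 genes. Cxadr was 4.70-fold higher in the KO-labelled libraries, at 90.9 ± 8.91 against 19.3 ± 2.44 CPM (log2 fold change 2.23, SE 0.17, edgeR adjusted p = 0.000903). Anxa6 was 2.16-fold lower, at 70.0 ± 1.74 against 151 ± 21.5 CPM (log2 fold change -1.11, SE 0.12, edgeR adjusted p = 0.0177). No other gene was called, and 1008 had an unadjusted p under 0.05, where chance gives 781. DESeq2 called 67 higher and 39 lower, and the authors' deposited table has 84 higher and 38 lower. The Anxa6 call ended by edgeR without WT trained replicate 2 (adjusted p = 0.0641) or 3 (0.111), or KO trained replicate 1 (0.164), 2 (0.146) or 3 (0.133), and in a fit of the 6 libraries compared (0.183). It also ended without KO replicate 2 of both treatments (edgeR adjusted p = 0.0835). Without KO trained replicate 3 the higher genes numbered 2. Within the first series of animals, edgeR gave Cxadr 2.29 (adjusted p = 0.00964) and Anxa6 -1.10 (adjusted p = 1.00). Both called genes were shared between house control and trained mice, which share no library (Fisher's exact test, p = 8.2e-09, against 0.000128 shared genes expected of independent lists). This p may be too small, because both contrasts take each gene's spread from the same fit and the test takes genes as independent. Across genes, which are not independent replicates, the 2 genotype effects correlated with r = 0.42 (Pearson) and 0.43 (Spearman).

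CA1 pyramidal neuron markers lay higher in KO-labelled trained mice, with all 8 members positive and a median log2 fold change of 0.81. Mpped1 was at 1.02 (SE 0.33) and Htr1a, the serotonin 1A receptor, at 0.91 (SE 0.32). Both were among the 3 members that passed adjusted over the list alone, and 0 passed over all genes. The list's camera call was lost (adjusted p = 0.216 with an estimated correlation). Dentate granule neuron markers lay lower, with 15 of 15 members negative, a median of -0.49 and Prox1 at -0.86 (SE 0.45), and an adjusted p = 0.79 with an estimated correlation. Markers of neighbouring regions also had medians away from 0. Those of the striatum and septum (neighbouring region) had a median of 1.84 (14 of 15 positive, adjusted p = 0.79 with an estimated correlation), which was -0.18 without KO trained replicate 2 (camera adjusted p = 0.928). Those of the thalamus (neighbouring region) had a median of -0.43 (adjusted p = 0.899 with an estimated correlation), and camera's call ended without WT trained replicate 3 (adjusted p = 0.866) or KO trained replicate 1 (0.149) or 2 (0.0882). Cholesterol biosynthesis genes had a median of 0.17 (22 of 24 positive, adjusted p = 0.416 with an estimated correlation). Camera called 10 of 36 lists here (16 without WT trained replicate 2), and none held with an estimated correlation.

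Averaged over both treatments, 60 genes were higher and 30 lower in the KO-labelled libraries. Cxadr led the higher genes (4.14-fold, log2 fold change 2.05, SE 0.12, edgeR adjusted p = 6.11e-05). Next came Pirt, a regulator of TRPV1 channels (3.79-fold, 0.537 ± 0.232 to 2.02 ± 0.602 CPM), and Clcn1, the skeletal muscle chloride channel whose splicing muscleblind proteins control (2.35-fold, 1.03 ± 0.141 to 2.44 ± 0.883 CPM; SD, n = 6 each). Arhgap33 rose 2.31-fold (77.0 ± 9.61 to 178 ± 42.5 CPM) and Fam205c from 2.78 ± 0.396 to 6.38 ± 1.26 CPM. The lower genes were led by Anxa6 (2.12-fold, edgeR adjusted p = 0.000729), Tomm34, a mitochondrial import factor (1.56-fold), Bmp1, a procollagen-processing protease (1.51-fold), Spata13 (1.46-fold) and Rpusd1 (1.42-fold). Their edgeR adjusted p ran from 0.000729 to 0.0473, and those of the higher 5 from 6.11e-05 to 0.0403. Among all 15622 genes tested, the 6 KO-labelled and 6 WT values did not overlap in 278, where chance gives 0.216% of genes. That share is an average over all splits. Because genes are not independent, an excess over it does not by itself show an effect of genotype. Leaving out any 1 library did not end the edgeR calls of Cxadr, Anxa6 and Tomm34. Those of Arhgap33 and Fam205c ended without KO trained replicate 1 (edgeR adjusted p = 0.0575 for both) or WT trained replicate 3 (0.0702 for both). The other calls held without WT house control replicate 1 but ended without most other libraries, at an edgeR adjusted p of up to 0.0817 for Pirt, 0.12 for Clcn1, 0.117 for Bmp1, 0.112 for Spata13 and 0.104 for Rpusd1. Within the first series of animals Cxadr alone of the named genes was called (edgeR adjusted p = 0.00173). Most changes were small, with a median of 1.39-fold and 8 genes beyond 2-fold.

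The count of calls moved by over 1.5 times in at least one direction whichever library was left out. Higher and lower genes numbered 203 and 65 without WT house control replicate 1, 24 and 7 without replicate 2 and 29 and 9 without replicate 3. They numbered 40 and 7, 24 and 9, and 5 and 3 without WT trained replicate 1, 2 or 3, and 44 and 19, 26 and 9, and 42 and 11 without KO house control replicate 1, 2 or 3. Without KO trained replicate 1, 2 or 3 they numbered 7 and 4, 38 and 11, and 17 and 4. Without WT house control replicates 2 and 3 and KO house control replicate 3, which had the highest thalamus marker means (4.67 to 5.23, log2), 1 gene was higher and 0 lower by edgeR, in a fit that leaves 1 WT house control library and takes its spread from the other groups, where all 12 libraries gave 2254 genes at an unadjusted p under 0.05 and DESeq2 512 higher and 213 lower. That fit does not remove all libraries rich in choroid plexus transcripts: the choroid plexus marker means of WT trained replicate 3 (6.56) and KO trained replicate 2 (5.55), which it keeps, lie above those of WT house control replicate 2 (6.38) and KO house control replicate 3 (5.11), respectively. KO replicate 2 of both treatments was rich in striatum, septum and neocortex transcripts, and without these libraries 18 genes were higher and 8 lower, and edgeR no longer called Clcn1, Fam205c, Bmp1, Spata13 and Rpusd1. With the animal series as a covariate 115 genes were higher and 51 lower, and within the first series alone 2 were higher and 0 lower; the second series holds 1 library per group and gives no test.

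**Figure D2:**
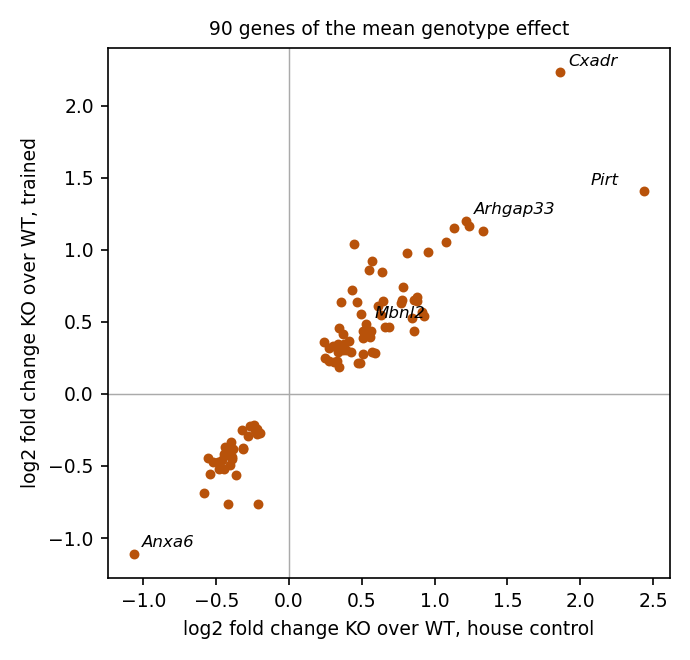
Log2 fold change of KO-labelled over WT libraries in house controls (horizontal axis) and in trained mice (vertical axis) for the 90 genes of the mean genotype effect, 1 point per gene, whose equal signs follow largely from being called on the mean of both values. Cxadr lies at 1.86 and 2.23 and Anxa6 at -1.06 and -1.11.

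Neuronal excitability and release genes leaned higher in the KO-labelled libraries over both treatments. Of 58 genes for voltage-gated calcium, sodium and potassium channels and their relatives, 45 were positive (median log2 fold change 0.18). Kcnn1, which encodes a calcium-activated potassium channel, was called over all genes (1.27-fold, edgeR adjusted p = 0.038), and 11 were higher and 1 lower adjusted over the list alone. Cacna1i (0.87, SE 0.17), Kcnq5 (0.62, SE 0.12) and Kcnab1 (0.38, SE 0.08) were among these 11. Of 45 genes of the presynaptic vesicle and release machinery, 37 were positive, with the vesicle priming gene Unc13b called over all genes (1.19-fold, edgeR adjusted p = 0.0497), and 8 higher and 1 lower adjusted over the list alone. Of 30 delayed activity-induced genes, 28 were positive. Nptx2, a secreted synaptic pentraxin, was called over all genes (1.57-fold, edgeR adjusted p = 0.0224), with 4 higher adjusted over the list alone. The channel list had an adjusted p = 0.448 with an estimated correlation, the presynaptic list an adjusted p = 0.545 with an estimated correlation, and the delayed activity-induced list an adjusted p = 0.102 with an estimated correlation, so all 3 camera calls were lost. By fry, which does not compare a list with other genes, the delayed activity-induced list moved on balance (adjusted p = 0.00862). Without the 3 house control libraries rich in choroid plexus or thalamus transcripts, which leaves 1 WT house control library, the channel and presynaptic lists also lost their calls at the preset correlation (camera adjusted p = 0.103 and 0.326). Among rapid activity-induced (immediate early) genes, Nr4a1 was called over all genes, with a log2 fold change of 0.75 (SE 0.11, edgeR adjusted p = 0.0225), and the list had an adjusted p = 0.448 with an estimated correlation. That list's preset call ended without WT house control replicate 1 or 2 (camera adjusted p = 0.0824 and 0.0636) or KO house control replicate 1 (0.0995).

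Markers of other cells and regions also had medians away from 0 in the same contrast. Leptomeningeal fibroblast markers had a median of -0.65 and dentate granule neuron markers of -0.41, with all 17 and all 15 members negative, and each list had an adjusted p = 0.545 with an estimated correlation. Those of choroid plexus epithelium had a median of -1.37 with all 19 negative (adjusted p = 0.73 with an estimated correlation). Camera's call of that list ended without WT house control replicate 3 (adjusted p = 0.177), WT trained replicate 3 (0.248), KO house control replicate 2 (0.0941) or KO trained replicate 1 (0.15). CA1 pyramidal neuron markers had a median of 0.64 with all 8 positive (adjusted p = 0.448 with an estimated correlation). Markers of the striatum and septum (neighbouring region) had a median of 0.99 with 14 of 15 positive and were not called (camera adjusted p = 0.0938). Their median was 0.08 without KO trained replicate 2, and they were called without WT house control replicate 3 (camera adjusted p = 0.00913), KO house control replicate 1 (0.0232) or 3 (0.0406), or KO trained replicate 1 (0.00489) or 3 (0.0291). Markers of the thalamus (neighbouring region) had a median of -0.52 with 14 of 17 negative (adjusted p = 0.705 with an estimated correlation), and camera's call ended without WT house control replicate 3 (adjusted p = 0.0857), WT trained replicate 3 (0.0969) or KO house control replicate 1 (0.0763). Those of endothelium had a median of -0.13 with 10 of 14 negative (adjusted p = 0.694 with an estimated correlation), and camera's call ended without replicate 1 of the WT house controls (adjusted p = 0.168), replicate 3 of the WT trained mice (0.0668) or replicate 2 of the KO house controls (0.116).

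The edgeR calls of Nptx2, Nr4a1, Kcnn1 and Unc13b also depended on single libraries. Nptx2 was not called without WT house control replicate 2 (adjusted p = 0.0547), WT trained replicate 3 (0.0811) or KO trained replicate 1 (0.071) or 3 (0.0542). Nr4a1 was not called without WT trained replicate 2 (0.0505) or 3 (0.0811), KO house control replicate 2 (0.0535) or KO trained replicate 1 (0.0553). Kcnn1 was called by edgeR only when the library left out was WT or KO house control replicate 1, with an adjusted p of up to 0.103 otherwise, and Unc13b only when it was WT trained replicate 1, with up to 0.136 otherwise. Without KO replicate 2 of both treatments edgeR called Nptx2 (adjusted p = 0.0493) and none of the other 3.

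In KO-labelled mice, training raised the list of immediate early genes, the transcription factors and synaptic genes switched on by neuronal activity. Nr4a1 had 42.4 ± 4.75 CPM in house controls and 77.7 ± 15.1 CPM after training (1.83-fold), Fos 5.92 ± 1.05 and 19.8 ± 0.714 CPM, and Egr2 0.524 ± 0.371 and 3.54 ± 0.584 CPM (SD, n = 3 mice each). With Egr4 (1.75-fold) they are among 10 of 44 members called higher adjusted over the list alone, with 0 lower. None passed over all genes by edgeR, where the smallest adjusted p was 1.00. The authors' deposited table calls 6 genes higher over all genes, all of them members of this list: Fos (adjusted p = 7.66e-18), Nr4a1 and Egr2 (0.00539 each), Arc (0.0146), and Egr4 and Npas4 (0.0249 each). The list had a median log2 fold change of 0.22 and 34 of 44 members positive, and its call held with an estimated correlation (camera adjusted p = 1.19e-25, and adjusted p = 0.00087 with an estimated correlation). Its mean log2 level was at most 4.12 in the 3 house controls and reached 4.47 in the 3 trained libraries, with no overlap. In the same contrast CA1 pyramidal neuron markers had a median of 0.42 with all 8 positive (adjusted p = 0.386 with an estimated correlation). Immature dentate neuron and neural progenitor markers had a median of -0.50 with 11 of 12 negative (adjusted p = 0.124 with an estimated correlation). Markers of mature oligodendrocyte and myelin had a median of -0.53 with 18 of 19 negative (adjusted p = 0.742 with an estimated correlation), and camera's call of them ended without KO house control replicate 2 (adjusted p = 0.88) or KO trained replicate 1 (0.483).

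In WT mice the same list had a median log2 fold change of 0.17 with 32 of 44 members positive (camera adjusted p = 1.86e-05). That call was lost, at an adjusted p = 0.0958 with an estimated correlation. The mean log2 level of the list was at most 4.14 in the 3 house controls and at least 4.19 in the 3 trained libraries, again with no overlap. Dusp5, a phosphatase acting on ERK, was called higher adjusted over the list alone, from 7.81 ± 1.70 to 14.5 ± 1.35 CPM (log2 fold change 0.90, SE 0.19). Nr4a1 was at 0.52 (SE 0.15), Egr4 at 0.50 (SE 0.15) and Arc, the synaptic plasticity transcript, at 0.79 (SE 0.25), none of them called. Averaged over the genotypes, 14 members were higher adjusted over the list alone, and the list held with an estimated correlation (camera adjusted p = 5.7e-15, and adjusted p = 0.00563 with an estimated correlation). Delayed activity-induced genes followed with Homer1 at 0.48 (SE 0.10), Crem at 0.36 (SE 0.08) and Gpr3 at 0.42 (SE 0.11), the 3 of 30 called adjusted over the list alone. That list had an adjusted p = 0.0516 with an estimated correlation.

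**Figure D3:**
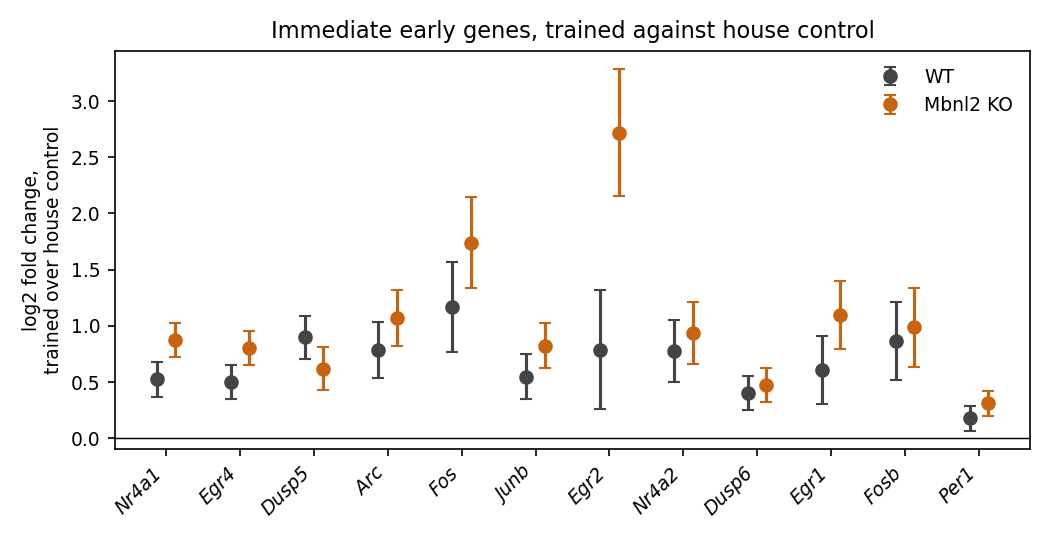
Log2 fold change of trained over house control mice with its SE for the 12 immediate early genes with the smallest unadjusted p in the mean training effect, in WT and in KO-labelled mice (3 mice per group), whose equal signs follow largely from that choice. The fitted values run from 0.18 for Per1 in WT to 2.72 for Egr2 in KO-labelled mice.

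By edgeR, 0 genes passed in either direction with training in WT mice (1534 at an unadjusted p under 0.05; DESeq2 3 higher and 13 lower), 0 in KO-labelled mice (471; DESeq2 4 and 3) and 0 on average over the genotypes (1744; DESeq2 25 and 44). Chance gives 781 genes at an unadjusted p under 0.05, above the 471 of KO-labelled mice and below the 1534 and 1744. The authors' deposited tables have 4 higher and 15 lower in WT and 6 higher and 8 lower in KO mice at an adjusted p under 0.05. The smallest edgeR adjusted p was 0.178, for Rasl11b in the mean effect. By edgeR 1 gene was higher in WT without WT house control replicate 3, and 1 in the mean effect without that library or without WT trained replicate 3.

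Vascular and connective tissue genes lay lower in trained than in house control WT mice. All 14 endothelial markers were negative, with a median log2 fold change of -0.49, and 10 were lower adjusted over the list alone, among them Pecam1 (-0.42, SE 0.10), Slco1a4 (-0.55, SE 0.13), Itm2a (-0.51, SE 0.15) and Ptprb (-0.54, SE 0.16). All 11 pericyte and smooth muscle markers were negative, and 5 were lower adjusted over the list alone, with Pdgfrb at -0.62 (SE 0.14) and Vtn at -0.69 (SE 0.18). Both lists had an adjusted p = 0.0958 with an estimated correlation, and 0.0367 by fry. Of 60 collagen, laminin and fibrous matrix genes 54 were negative, and Lama4 (-0.94, SE 0.20) and Eln (-1.16, SE 0.28) were lower adjusted over the list alone (adjusted p = 0.372 with an estimated correlation). Interferon and antigen presentation genes had a median of -0.67 and an adjusted p = 0.372 with an estimated correlation. Leptomeningeal markers had a median of -1.15 and an adjusted p = 0.389 with an estimated correlation, and Ttr was again uneven, at 2879, 14.5 and 6937 CPM in the trained WT libraries. Markers of other tissue lay lower as well. The median was -1.23 for ependymal cell markers (13 of 13 negative, adjusted p = 0.572 with an estimated correlation) and -0.92 for thalamus markers (15 of 17, adjusted p = 0.562 with an estimated correlation). It was -0.68 for markers of mature oligodendrocyte and myelin (19 of 19, adjusted p = 0.616 with an estimated correlation), whose camera call ended without WT house control replicate 2 (adjusted p = 0.0584) or 3 (0.0638) or WT trained replicate 2 (0.237). It was -1.57 for markers of the striatum and septum (neighbouring region) (14 of 15, adjusted p = 0.607 with an estimated correlation), whose camera call ended without WT house control replicate 3 (adjusted p = 0.208).

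In KO-labelled mice, microglial markers lay lower after training (14 of 15 negative, median log2 fold change -0.32). The libraries overlapped, however. The list's mean log2 level was 4.44, 4.74 and 4.83 in house control replicates 1, 2 and 3 and 4.45, 4.29 and 4.43 in trained replicates 1, 2 and 3. Csf1r (-0.39, SE 0.10), Cx3cr1 (-0.36, SE 0.09), Trem2 (-0.62, SE 0.17) and C1qb (-0.43, SE 0.14) were the 4 lower adjusted over the list alone, and the list had an adjusted p = 0.124 with an estimated correlation. Astrocyte markers had a median of -0.21, 0 members called and an adjusted p = 0.0787 with an estimated correlation. Gfap was at 1951 CPM in KO house control replicate 3 against 290 to 613 CPM in the other libraries. Markers of the thalamus (neighbouring region) had a median of -0.64 (adjusted p = 0.497 with an estimated correlation), and Slc17a6 was at 53.4 CPM in that same replicate 3, without which the median was -0.13 (camera adjusted p = 0.513).

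The effect of training was compared between the genotypes by their interaction. By edgeR 0 genes differed, and DESeq2 called 0 higher and 0 lower. At an unadjusted p under 0.05 there were 235 genes by edgeR, fewer than the 781 expected by chance. For immediate early genes the interaction was 0.35 (SE 0.22) for Nr4a1, 0.57 (SE 0.56) for Fos, 0.28 (SE 0.35) for Arc and 1.93 (SE 0.77) for Egr2 on the log2 scale, none of them called. Camera called 15 of 36 lists (10 without WT house control replicate 2 and 9 without replicate 3), and none held with an estimated correlation, the immediate early list among them (median 0.12, adjusted p = 0.498 with an estimated correlation). The median of these rapid activity-induced (immediate early) genes was 0.06 without WT house control replicate 3. It was also 0.06 without KO replicate 2 of both treatments, where camera called 9 lists and no longer this list (adjusted p = 0.0738).

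**Figure D4:**
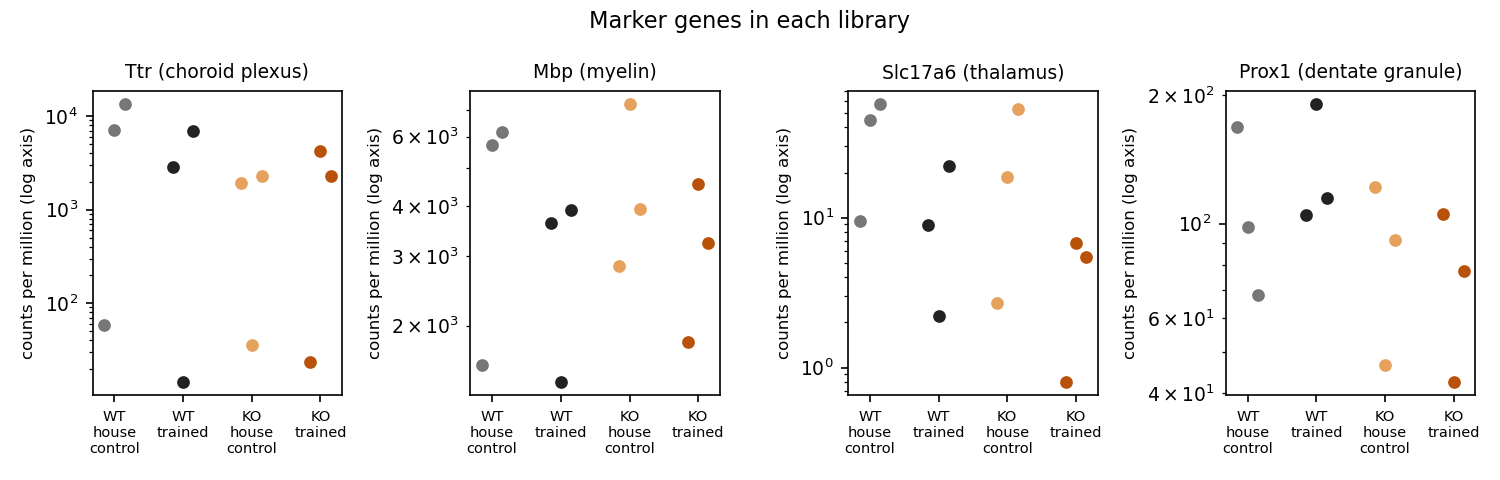
Counts scaled to library size (CPM), on log axes, of marker genes of choroid plexus (Ttr), myelin (Mbp), thalamus (Slc17a6) and dentate granule neurons (Prox1), 1 point per library. Ttr spans 14.5 to 13366 CPM, and libraries of 1 group lie far apart in each panel.

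Markers of neighbouring tissue varied widely within groups. Ttr ran from 14.5 to 13366 CPM, Mbp from 1445 to 7244 CPM, Slc17a6 from 0.806 to 57.0 CPM and Prox1 from 42.7 to 190 CPM over the 12 libraries. The first principal component of log2 CPM held 44.4% of the variance and placed WT house control replicates 2 and 3 at one end and WT trained replicate 2 and KO trained replicate 1 at the other. The second component (15.8%) set apart KO house control replicate 2 and KO trained replicate 2, at 51.4 and 37.7 where the other libraries were at most 5.25. Their mean log2 levels were 5.05 and 5.26 for striatum and septum markers, against 4.85 and 3.28 in WT house control replicates 3 and 2 and at most 2.54 in the rest, and 5.46 and 5.33 for neocortex markers, against at most 4.73 in the rest. In no comparison did camera call the lists of neural splicing regulators, perineuronal net components, GABA receptors, neuropeptides, clock genes, interneurons, CA3 neurons, neocortex or sex markers, and the largest of their medians was 0.35, for CA3 neurons between the genotypes in house controls.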

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

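The fit with the marker component and the fit without 2 KO libraries were chosen only after the results were seen; the other tests in this part were written down before.

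Training effects that differed between the genotypes drew attention in 15 lists, by camera's test of the interaction at its preset correlation. With an estimated correlation none of the 15 passed, the adjusted p then running from 0.498 to 0.914. The effect was less negative in KO-labelled than in WT mice for collagens, laminins and fibrous matrix (adjusted p = 6.04e-09, medians -0.74 in WT and -0.17 in KO-labelled mice), interferon response (4.11e-09, -0.67 and -0.07), endothelium (2.44e-06, -0.49 and -0.16), pericytes (8.75e-06, -0.62 and -0.05) and leptomeningeal fibroblasts (1.34e-11, -1.15 and -0.12). Signs of the medians were opposite for choroid plexus (0.011, -0.98 and 0.34), striatum and septum (0.00153, -1.57 and 0.27), CA2 neurons (0.0494, 0.14 and -0.10) and oxidative phosphorylation (0.00783, -0.03 and 0.03). The medians were 0.05 and 0.42 for CA1 neurons (0.0198), -0.10 and -0.32 for microglia (0.00108), 0.23 and 0.11 for postsynaptic genes (0.0265), 0.27 and 0.08 for presynaptic genes (2.28e-06), 0.22 and 0.09 for channels (0.00899), and 0.17 and 0.22 for immediate early genes (0.00771). Of 100 splits that keep the treatments, 47 called at least the 15 lists of the real one and the highest other called 20, so chance is not excluded for this count.

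The first pattern weighed is the lower level of endothelial and other vascular, meningeal and matrix genes in trained WT mice. With the leptomeningeal and choroid plexus marker means as covariates, the endothelial difference went from -0.42 (SE 0.09) to -0.25 (SE 0.07) on the log2 scale, between the bounds set for and against different amounts of such tissue in the dissected pieces. Without WT house control replicate 1 the endothelial median went from -0.49 to -0.34, again between the bounds for a single library as the source. Neither explanation can be told apart from an effect of training, because both values fell between the bounds set beforehand, and an effect of training on vessels stays open as untested.

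The second pattern is the larger rise of rapid activity-induced (immediate early) genes with training in KO-labelled mice. The median interaction of the list was 0.12 with all libraries and 0.0636 without WT house control replicate 3, so 1 library may account for part of it, and it was 0.06 without KO replicate 2 of both treatments, which held more striatum, septum and neocortex transcripts. With the marker component as a covariate the median was 0.123, no smaller, yet the members spread widely (quartiles 0.00 and 0.29 without it), which keeps a mix of regions open. An effect of genotype on the response stays open, since camera with an estimated correlation did not call the interaction.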

How the results depend on the processing

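The settings with the marker component, without 3 house control libraries rich in choroid plexus or thalamus transcripts (other libraries as rich in choroid plexus transcripts were kept), without 2 libraries rich in striatum, septum and neocortex transcripts, and with DESeq2 on 6 libraries were chosen only after the results were seen; the others were planned. No paired analysis was possible because replicate numbers follow accession order only. Calls are given as higher and lower by edgeR's quasi-likelihood test unless another tool is named, and the cause was not tested unless stated. DESeq2 on 12 libraries called 155 and 47 between genotypes in house controls (1 and 1 by edgeR), 67 and 39 in trained mice (1 and 1), 3 and 13 with training in WT (0 and 0), 4 and 3 in KO-labelled mice (0 and 0), 512 and 213 for the mean genotype effect (60 and 30) and 25 and 44 for the mean training effect (0 and 0), and 48 genotype calls were shared between treatments (2 by edgeR). DESeq2 on the 6 libraries compared called 58 and 16, 90 and 42, 4 and 15, and 6 and 8 in the 4 pairwise comparisons in that order. With the animal series as a covariate, 3 genes were higher between genotypes in house controls, 3 in trained mice, and 115 and 51 were called for the mean genotype effect. With the first animal series only, which has fewer libraries, 0 were lower in either treatment, 2 and 0 were called for the mean genotype effect and 1 was higher for mean training. With the marker component, 2 and 4 were called in house controls and 210 and 133 for the mean genotype effect. Without the 3 libraries, which leaves 1 WT house control library that is assumed to vary like the other groups, 0 and 0 were called in house controls, 0 were lower in trained mice, 1 and 0 were called for the mean genotype effect, and the log2 fold change of Mbnl1 with training in WT turned from -0.18 to 0.107. Without the 2 libraries, 0 and 0 were called in house controls, 0 were lower in trained mice, 18 and 8 were called for the mean genotype effect, and camera called 9 lists for the interaction. With only the 6 libraries compared, 0 and 0 were called in house controls and 0 were lower in trained mice. Without a filter on low counts, 17 were lower for the mean genotype effect. Leaving out each library gave 0 to 11 higher and 0 to 1 lower in house controls, 1 to 2 higher and 0 to 1 lower in trained mice, 0 to 1 higher with training in WT, 5 to 203 higher and 3 to 65 lower for the mean genotype effect, 0 to 1 higher for mean training, and 9 to 16 lists in trained mice and for the interaction. Camera with an estimated correlation called 0, 0, 0 and 1 lists in the 4 pairwise comparisons, 0 for mean genotype, 1 for mean training and 0 for the interaction, where fry called 1, 0, 4, 1, 1, 4 and 0 and camera at the preset correlation 18, 10, 18, 17, 16, 20 and 15. Of the values of named genes under other settings, 370 kept direction and side of the threshold, 101 lost the call, 8 gained one and 1 reversed. Median-of-ratios scaling moved the median log2 fold change of all genes by at most 0.0107. Depth limits statements on genes near the floor, such as Mbnl3.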

Other observations

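The tests of genomic position, the fit with the marker component and the fit without 3 libraries were chosen only after the results were seen; the counts of other splits were planned.

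Glutamate receptor genes leaned higher in KO-labelled libraries over both treatments, with 32 of 35 members positive and Grin2d at 0.43 (SE 0.10), the 1 member called adjusted over the list alone. CA1 markers had all 8 members positive and 4 higher adjusted over the list alone. Cholesterol biosynthesis genes had 23 of 24 members positive and 4 higher adjusted over the list alone, with Srebf2, the transcription factor of that pathway, at 0.24 (SE 0.06). Each of the 3 lists had an adjusted p = 0.448 with an estimated correlation, and 0 members were called over all genes by edgeR. Without the 3 house control libraries rich in choroid plexus or thalamus transcripts, which leaves 1 WT house control library, the ionotropic and metabotropic glutamate receptors lost camera's call at the preset correlation (median 0.09, adjusted p = 0.144).

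Trained mice of both genotypes together had lower medians of endothelial markers (-0.29, 14 of 14 negative), and 10 were lower adjusted over the list alone, among them Pecam1 at -0.32 (SE 0.07) and Slco1a4 at -0.35 (SE 0.09). Most of this came from WT mice, with a median of -0.49 and 10 lower adjusted over the list alone. In KO-labelled mice the median was -0.16, with 11 of 14 negative and 0 lower adjusted over the list alone. Astrocyte markers had a median of -0.21 with 14 of 14 negative and 0 called adjusted over the list alone, with Aqp4, the water channel of astrocyte endfeet, at -0.44 (SE 0.14). Both lists had an adjusted p = 0.187 with an estimated correlation, and by fry 0.0403 and 0.0411. Glucocorticoid-responsive genes had a median of 0.21, with 21 of 29 positive, 0 called adjusted over the list alone and Hif3a at 0.67 (SE 0.18), and an adjusted p = 0.332 with an estimated correlation. Genes of mature oligodendrocyte and myelin had a median of -0.58 (19 of 19 negative, 0 called, adjusted p = 0.549 with an estimated correlation), which turned to 0.48 with the marker component, made in part from these markers, as a covariate. Within each genotype, thalamus (-0.92 in WT and -0.64 in KO-labelled mice) and ependymal cell markers (-1.23 and -0.60) also had lower medians after training. The thalamus median in KO-labelled mice depended largely on house control replicate 3. Its thalamus marker mean was 5.09 (log2), against 3.04 and 3.54 in KO house control replicates 1 and 2. Choroid plexus markers differed in sign (-0.98 and 0.34).

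The third pattern is the position of the genes called between the genotypes. Within 10 Mb of Mbnl2, and leaving out Mbnl2 itself here and below, 2 of 34 tested genes were called, Dzip1 and Uggt2, against 84 of 14973 elsewhere (Fisher's exact test, p = 0.0162). These genes lie near each other (Dzip1 ends at 118925460 and Uggt2 starts at 118985039). They are therefore taken as a single locus, and the p, which takes them as independent, is too small. Windows of 2 and 5 Mb held the same 2 called genes. Within 20 Mb 3 of 55 tested genes were called (Fisher's exact test, p = 0.00385). The gene added there, Commd6, does not lie near the other 2. Of the called genes with coordinates, 79 of 86 lie outside chromosome 14, which argues against local effects of a linked segment as the source of all calls. Position cannot decide whether such a segment acts on genes of other chromosomes. Outside chromosome 14, pairs of called genes within 1 Mb numbered 7, as many as in a share of 0.259 of random sets, which leaves unlinked strain segments open. A linked segment of the 129 or C57BL/6 strain, or a local effect of the targeted allele, may account for the calls near Mbnl2, and these 2 cannot be separated here.

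Other splits of the same libraries were fitted for each count. The mean genotype effect called 90 genes, and 3 of 100 splits, the real one included, called as many, a share under the 0.05 set beforehand. This argues against chance for this count without excluding it, since another split called far more. The splits kept the treatments but moved libraries across the animal series. The highest other split called 1982, for a reason that was not tested. With the treatments pooled, no list of markers separated its sides without overlap. Within each treatment myelin markers did separate them. Their mean log2 levels were at least 7.48 against at most 6.73 in house controls, and at least 6.63 against at most 6.41 in trained mice. Over both treatments the sides had means of 7.18 and 5.94 for myelin markers and of 5.47 and 2.85 for choroid plexus markers. By edgeR the mean training effect and the interaction called 0 genes (DESeq2 25 higher and 44 lower, and 0). At an unadjusted p under 0.05 they had 1744 and 235 genes by edgeR, where chance gives 781. With 0 genes called, all 100 splits called as many by construction and nothing is tested. The highest other splits called 8 and 1982. By permutation of the libraries over 100 splits, 3, the real one included, gave the immediate early list as small a camera p as the real mean training effect (1.58e-16). The most extreme other split gave 4.17e-21. The share is under the 0.05 set beforehand, which argues against chance without excluding it. Lists called in the mean genotype effect numbered 16, with 29 of 100 splits as many and 20 in the highest other; in the mean training effect 20, with 9 of 100 and 23. Chance is not excluded for either count of lists. The 10 splits of 6 libraries are too few for a share under 0.05. There the real and highest other counts of genes were 2 and 0 between genotypes in house controls, 2 and 0 in trained mice, 0 and 0 with training in WT and 0 and 0 in KO-labelled mice, with 1, 1, 10 and 10 splits as large, the 10 by construction. The counts of lists were 18 and 17, 10 and 18, 18 and 19, and 17 and 21, with 1, 9, 2 and 2 splits as large. The camera p of the immediate early list was 4.66e-06 in WT, against 1.11e-09 in the most extreme other split, and 3.3e-27 in KO-labelled mice, against 5.31e-06, with 2 and 1 splits as extreme.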
